A study of Mus musculus with 6 samples.

How the data were processed

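Single kidney cells were measured in 6 samples from C57BL/6J mice aged 16 weeks. Per the labels' protocols, 3 samples received furosemide at 70 mg/kg body weight and 3 received vehicle for 1 week, in a gel diet that held 104 µmol sodium per kcal. Kidneys were dissociated mechanically and with collagenase. Messenger RNA of single cells was captured on BD Rhapsody beads, and whole-transcriptome and targeted libraries were made and sequenced. Per the submitters' processing notes, Bowtie2 2.2.9 was used. The genome build, the counting step and the correction of molecular barcodes were not given in the sources used here.

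The deposited table of counts holds whole numbers per cell and gene, for 456 genes and 22154 cells. Per the file headers and names, the authors had removed doublets and a mixed cluster and had brought cell numbers to the same size in both treatments, here 11077 cells each. Whether a count is a molecule or a read was not stated, and neither was which of both assays gave the table. Its 456 genes are a chosen panel, so that a gene's share of a cell's counts is its share within that panel. The deposited annotation gives other values per cell: the library number, the treatment, 15 cell classes, 19 finer classes and a second clustering with 22 named clusters. Its columns hold each library under a single treatment, with libraries 1, 3 and 5 under vehicle and libraries 2, 4 and 6 under furosemide. Replicate numbers of the sample titles could not be joined to library numbers, so samples are named by treatment and library. Nothing in the labels says that replicates came from separate animals beyond being separate samples. The p-values then measure only the spread between these samples.

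Counts were summed per library and authors' class. The smallest sum held 12 cells, above the minimum of 10 set for a test. The 3 proximal classes were tested each and also summed, and all cells of a library were summed as a whole-sample view. Each sum was fitted on its own with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr by group, robust glmQLFit and glmQLFTest). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in its class. Log2 fold changes are furosemide over vehicle as edgeR's fit gave them at its default settings, with their standard error (SE). A prior count of 2 entered only the log2 CPM of the list tests and of the limma test on differences. Levels are TMM-scaled counts relative to the total of the sum (CPM), as mean ± standard deviation (SD) over 3 libraries, unless they are called plain CPM. Differences of the treatment effect between the summed proximal classes and the thick ascending limb, distal convoluted tubule, connecting tubule and cortical principal cells (4 pairs) were tested as interactions, with the library as a block.

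Gene lists were 32 in number, of which 17 had at least 5 tested members in some class, giving 198 pairs of list and class. They were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, which compares a list's genes with all other genes. They were tested again with an estimated correlation and with fry, which asks whether a list's genes moved, on balance, in a single direction. The lists on insulin-like growth factor (IGF) signalling and on the cell cycle were written knowing that the study reports on these topics, so their counts are not independent evidence of direction. Shares of cells per class were compared by two-sided exact permutation over all 20 assignments of libraries, adjusted by Benjamini-Hochberg over the classes. With 3 against 3 libraries such an exact test cannot go below p = 0.1 and so cannot reach 0.05. Cells with cell-cycle transcripts were cells with counts of 2 or more of 18 listed genes, of which the panel held 2, Birc5 and Mki67. Where a treatment had no such cell in a class before thinning, the share that 3 counts would give is printed as its upper limit, which covers counting error only.

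Genes are named by a fixed rule. Per class it takes the 5 called genes with the smallest adjusted p in each direction whose libraries did not overlap between treatments, or the 3 with the smallest p in each direction where none was called. It adds called list members, up to 10 per class, and 24 core genes, most of them of the nephron, each in its class of highest level. The core genes include Birc5, Mki67, Igf1r, Igfbp1 and Igfbp5. They were set down knowing that the study reports on Birc5 and on IGF signalling in these samples. Of these core genes 23 were in the panel, which lacked Slc34a1. For differences between segments it takes the 5 with the smallest adjusted p in each direction. Not every gene that the rule takes is named in the text. Genes named outside the rule are said to be so, and they were chosen after their values were seen. The tests, lists, naming rule and alternatives were fixed before the data were examined, except for the choices named below. The tests of segments against the proximal tubule were among those fixed, but not that its 3 classes would be summed for them.

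The alternatives tried were DESeq2-type size factors (RLE), library size alone, no filter on low counts, DESeq2 1.42.0 and limma-voom. Others were equal cell numbers per library, removal of cells with the top 5% of totals in their class, and leaving out each library in turn. For shares they were tubular cells as the total and edgeR on cell numbers, and for cell-cycle transcripts 1 or more transcripts and cells thinned to a fixed depth. Chosen after seeing the data were the second clustering, summing the 3 proximal classes, thinning of all cells to a fixed total, leaving out of genes at under 5% of their highest class, and shares without the thick ascending limb. The pipeline was tested on simulated data with 40 changed genes in each of 5 simulations. At a 2-fold change it recovered 44.6% of the changed genes in thick ascending limb sums, 64.6% in distal convoluted tubule sums and 61.5% in connecting tubule sums. At a 4-fold change these shares were 83.1%, 100.0% and 89.2%, and at a 1.5-fold change 5.7%, 27.1% and 18.6%. Changed genes were drawn only from genes above a minimum count. In thick ascending limb sums 4, 29 and 54 changed genes were recovered at 1.5-fold, 2-fold and 4-fold, beside 9 false calls. These were 19, 42 and 65 beside 11 in distal convoluted tubule sums, and 13, 40 and 58 beside 9 in connecting tubule sums. False calls thus made up more than the nominal 5% of calls in each. The list test found its simulated list in 20 of 20 simulations. For differences from the proximal tubule, 12.3% of 2-fold and 66.2% of 4-fold differences were recovered in the thick ascending limb, and 10.8% and 86.2% in the distal convoluted tubule. Recovered differences at 1.5-fold, 2-fold and 4-fold were 2, 8 and 43 beside 7 false ones in the former. In the latter they were 2, 7 and 56 beside 3.

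Depth per library ran from 4819988 to 7635509 counts. All 5 genes at 0 in every cell stayed untested. Sequence reads were not used here, nor were the annotation's columns on potential doublets and on clusterings other than those named. Shares and distances were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Gene positions are from GENCODE M21 on GRCm38. No pair of libraries was a duplicate of another: Pearson's r between their log2 CPM over all cells, across genes, lay between 0.957 and 0.980, and genes are not independent replicates.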

Results

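The data are counts of a gene panel in 22154 single mouse kidney cells, from 3 samples given vehicle and 3 given furosemide, an inhibitor of the sodium-potassium-chloride cotransporter of the thick ascending limb. Vehicle libraries held 4082 cells and 6315516 counts (library 1), 3316 cells and 6097059 counts (library 3) and 3679 cells and 4819988 counts (library 5). Furosemide libraries held 3051 cells and 4928550 counts (library 2), 4439 cells and 7635509 counts (library 4) and 3587 cells and 5224330 counts (library 6). Median counts per cell were 1262.5, 1539.5 and 1073 in vehicle libraries 1, 3 and 5, and 1330.0, 1407 and 1218 in furosemide libraries 2, 4 and 6. Cells with 12 to 11485 counts were kept by the authors, and 35.2% of all values above 0 were a count of 1.

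The authors' 15 classes are named here as in the annotation. They are 3 proximal tubule classes (Proximal s1/s2, Proximal s1/s2/s3 and Proximal s2/s3), Thin Limb, thick ascending limb (TAL), distal convoluted tubule (DCT and DCT2) and connecting tubule (CNT). The others are principal cells of the cortical and outer medullary collecting duct (CCD principal, OMCD principal), intercalated cells of types A and B (AIC, BIC), Podocytes/Glom, Immune and mystery cells. Slc12a1, Cldn16, Egf and Umod were among the 10 leading genes of TAL, Trpm6 and Slc12a3 among those of DCT, and Trpv5, S100g and Slc8a1 among those of CNT. DCT2 led with 5 listed connecting tubule markers and 4 listed DCT markers. OMCD principal led with Aqp6 and Slc4a1, markers of type A intercalated cells, and held 2 listed principal cell markers. In the second clustering, OMCD principal cells fell in the clusters named AIC (241 cells) and AIC sub2 (132 cells) and in none named for principal cells. The authors' names were kept for both classes, but results under OMCD principal are not read as those of principal cells. Class borders rest on such leading genes, so a change in one of them can also move class sizes.

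The first question, from the series title, was how cells of each nephron segment adapt to a week of furosemide, and the share of cells per class is the broadest view of it. TAL cells made up 23.7% ± 1.01 of vehicle libraries and 13.3% ± 2.13 of furosemide libraries (SD, n = 3), a log2 ratio of -0.84. DCT2 cells made up 1.43% ± 0.38 and 3.0% ± 0.516, a log2 ratio of 1.07, and CNT cells 3.63% ± 0.496 and 6.41% ± 1.49, a log2 ratio of 0.82. Proximal s2/s3 cells made up 17.1% ± 3.91 and 23.2% ± 0.939, and OMCD principal cells 2.05% ± 0.319 and 1.36% ± 0.241. In these 5 classes all furosemide libraries lay on one side of all vehicle libraries (exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow, adjusted p = 0.3). DCT cells made up 7.22% ± 1.36 and 9.91% ± 1.48, with overlapping libraries (exact permutation p = 0.2). No share passed at 0.05, which this test cannot reach. With edgeR on cell numbers the log2 change was -0.84 in TAL (adjusted p = 0.0154), 0.82 in CNT (0.0181) and 1.06 in DCT2 (0.00852), which passed. Shares of a fixed total are bound to each other: with TAL left out of the total, the log2 ratio was 0.64 in CNT, 0.88 in DCT2, 0.27 in DCT and 0.26 in Proximal s2/s3.

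**Figure D1:**
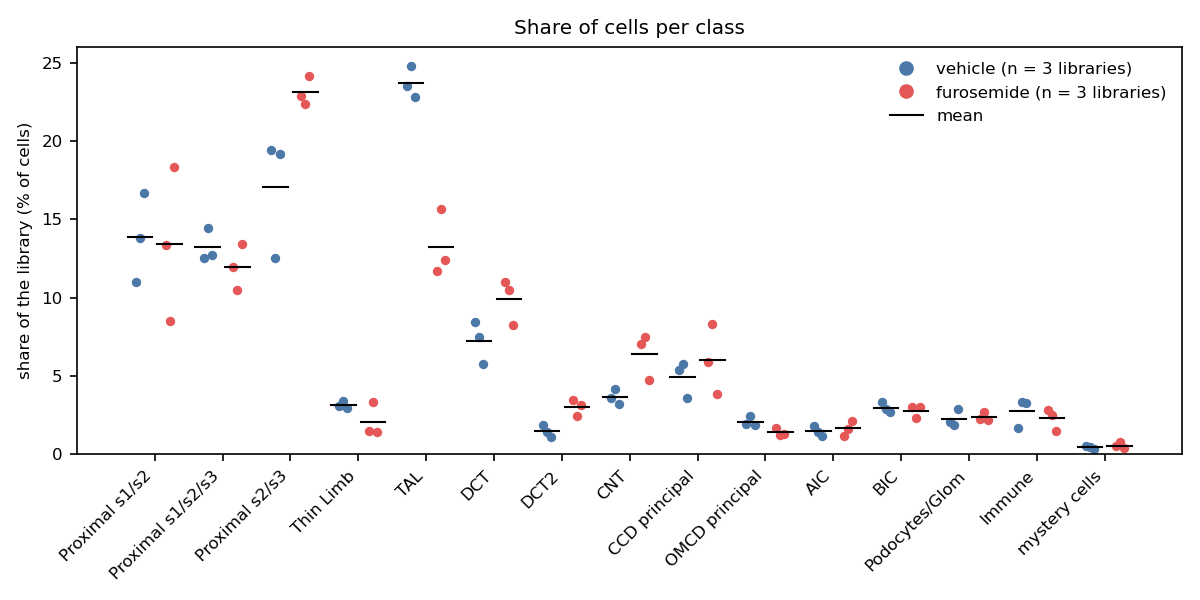
Share of each library's cells (percent, vertical axis) in each of the authors' classes, with a point per library, vehicle and furosemide side by side, and group means. TAL had a mean of 23.7% in vehicle libraries and 13.3% in furosemide libraries without overlap, and CNT and DCT2 lay higher with furosemide.

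In TAL cells, where furosemide acts, 15 of 317 genes passed edgeR's quasi-likelihood test, 5 higher and 10 lower with furosemide, and all 3 furosemide libraries lay apart from all 3 vehicle libraries for each of them. Pappa2, a protease that cleaves IGF-binding proteins and is known from the macula densa, rose from 29.6 ± 7.07 to 220.4 ± 69.8 CPM (log2 change 2.89 ± 0.30 SE, adjusted p = 0.0061). Cldn16, a claudin of the paracellular route for calcium and magnesium, rose from 3028 ± 64.9 to 6301 ± 1572 CPM (1.06 ± 0.20, adjusted p = 0.0426). Fxyd2, the gamma subunit of the sodium pump, fell from 1796 ± 122 to 753 ± 70 CPM (-1.26 ± 0.13, adjusted p = 0.0061). Slc12a1, the target of furosemide, did not pass (88521 and 98961 CPM, log2 change 0.16 ± 0.16, adjusted p = 0.653), nor did Umod, which encodes uromodulin (0.14 ± 0.17, adjusted p = 0.701), or Egf (0.38 ± 0.17, adjusted p = 0.34).

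Further TAL genes that rose were Wfdc2 (log2 change 0.91 ± 0.15, adjusted p = 0.0265) and Calb1 (1.66 ± 0.19, 0.00701), a calcium-binding protein of the DCT and connecting tubule. Calb1 in TAL stood at 0.104% of its level in its highest class, DCT2. Genes that fell were lipoprotein lipase Lpl (-1.09 ± 0.16, adjusted p = 0.0177), G6pc (-1.80 ± 0.27, 0.0177), cyclin Ccnd1 (-1.29 ± 0.19, 0.0177), Nr0b2 (-0.58 ± 0.10, 0.0358), Pdgfb (-1.97 ± 0.37, 0.0426) and Myc (-0.86 ± 0.17, 0.0426). G6pc, an enzyme of gluconeogenesis with its highest level in proximal cells, stood at 2.01% of that level in TAL. Outside the naming rule, and chosen after their values were seen, Gpx6 (-0.94), Ptgds (-1.91) and Adora2b (-1.31) also fell. Cldn16, Pappa2 and Gpx6 were among the 10 leading genes of TAL. Of TAL cells, 13.0% ± 1.35 held only Cldn16 of the claudin pair Cldn16 and Cldn10 in vehicle libraries and 16.9% ± 2.84 in furosemide libraries, while 32.5% ± 3.95 and 14.2% ± 1.97 held only Cldn10.

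By lists in TAL, of 16 tested genes of TAL salt transport 2 rose, among them Cldn16, and none fell, with 3 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.243). Of 8 genes of calcium and magnesium handling, 2 rose (Calb1 and Cldn16), also 2 when adjusted over the list alone (camera adjusted p = 0.0623). Of 17 genes of DCT salt transport, 2 rose, among them Calb1, and 1 fell (Fxyd2), against 3 and 1 adjusted over the list alone (camera adjusted p = 0.147). Of 19 IGF genes 1 rose, Pappa2, also 1 adjusted over the list alone (camera adjusted p = 0.981; median -0.07, mean -0.01). Of 9 genes of the epidermal growth factor (EGF) and other growth factor list, Pdgfb fell and 4 fell when adjusted over the list alone (camera adjusted p = 0.147). None of 7 immediate early genes of tissue dissociation passed (median log2 change -0.43, camera adjusted p = 0.147), and neither did any of 13 genes of sodium channel and aldosterone signalling over all genes (1 higher over the list alone). The split of 5 higher and 10 lower in TAL became 16 and 16 with DESeq2, 10 and 10 with equal cell numbers, 11 and 11 without the top 5% of totals and 13 and 15 with thinned cells, so the balance of directions depends on the setting. Leaving out a library gave counts of 7, 3 and 8 without vehicle libraries 1, 3 and 5, and 3, 4 and 21 without furosemide libraries 2, 4 and 6. Pappa2, Calb1 and Fxyd2 passed in each of these fits, while Cldn16 did not pass without furosemide library 2 (1.11, adjusted p = 0.0795) or vehicle libraries 1 (1.03, 0.104), 3 (1.11, 0.122) and 5 (1.09, 0.0966). The other named TAL genes that changed each missed the threshold without 3 to 6 of the 6 libraries, and Pdgfb also with limma-voom (-1.85, adjusted p = 0.0615). Myc also missed it with RLE size factors (-0.85, 0.0513), equal cell numbers (-0.79, 0.0721) and thinned cells (-0.88, 0.0648). In cells that held only Cldn16, Fxyd2 had the opposite sign (0.53 ± 0.28).

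In DCT cells, 13 of 275 genes passed, 8 higher and 5 lower with furosemide. Birc5, a survivin needed for cell division, rose from 11.3 ± 7.09 to 185.3 ± 98.1 CPM (log2 change 3.98 ± 0.53, adjusted p = 0.00517). Mki67, a marker of cycling cells, rose from 8.45 ± 5.59 to 107.3 ± 39.3 CPM (3.64 ± 0.50, adjusted p = 0.00517). Tfrc, the transferrin receptor and among the 10 leading DCT genes, rose from 3152 ± 905 to 7768 ± 1748 CPM (1.30 ± 0.23, adjusted p = 0.0113). Slc12a3, the thiazide-sensitive cotransporter, did not pass (97011 and 105037 CPM, log2 change 0.11 ± 0.14, adjusted p = 0.861), and neither did Fxyd2 (0.35 ± 0.15, adjusted p = 0.323).

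The glucose transporter Slc2a4 (0.88 ± 0.15, adjusted p = 0.0108), Inmt (1.1 ± 0.16, 0.00597), osteopontin Spp1 (0.69 ± 0.14, 0.0252) and the proton pump gene Atp6v1c2 (0.98 ± 0.20, 0.0227) also rose in DCT, as did Ckb (0.54), chosen after its value was seen. The heat shock gene Hspa1a (-1.20 ± 0.21, adjusted p = 0.0113), Thbs1 (-0.86 ± 0.15, 0.0113), Timp3 (-0.66 ± 0.15, 0.0404) and the prostaglandin receptor Ptger3 (-0.82 ± 0.20, 0.0481) fell. Slc12a1 fell in DCT (-1.23 ± 0.23, adjusted p = 0.0113), where it stood at 0.289% of its TAL level, and Atp6v1c2 stood at 0.757% of its level in its highest class. The split of 8 higher and 5 lower became 7 and 7 with RLE size factors, and 5 and 6 with library size alone. None of 17 genes of DCT salt transport passed, also none when adjusted over the list alone (camera adjusted p = 0.981; median -0.03, mean 0.01). None of 10 genes of calcium and magnesium handling (camera adjusted p = 0.797) and none of 15 IGF genes (0.38) passed either way. Of 16 genes of TAL salt transport, Slc12a1 and Ptger3 fell, also 2 adjusted over the list alone (camera adjusted p = 0.25). Of 6 injury genes Spp1 rose, and of 6 acid-base genes of intercalated cells Atp6v1c2 rose.

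Without vehicle library 5, no DCT gene passed edgeR's test (Birc5 3.79 and Mki67 3.56, adjusted p = 0.0529 each); counts were 5 and 10 without vehicle libraries 1 and 3, and 11, 11 and 9 without furosemide libraries 2, 4 and 6. Without vehicle library 1, Tfrc did not pass either (1.31, adjusted p = 0.0871), and Tfrc without vehicle library 5 was 1.09 (0.0529). Without cells in the top 5% of totals, Mki67 was 5.60, and with cells thinned to a fixed total Slc12a1 (-1.02, adjusted p = 0.0732) and Atp6v1c2 (0.68, 0.234) did not pass. Spp1, Timp3 and Ptger3 each missed the threshold without 5 of the 6 libraries, Atp6v1c2 without 4, and Hspa1a and Thbs1 without 2. Spp1 also missed it without the top 5% of totals (0.57, adjusted p = 0.0557), with library size alone (0.60, 0.0505) and in the second clustering (0.54, 0.0509), Atp6v1c2 with library size alone (0.88, 0.0505), Timp3 with equal cell numbers (-0.63, 0.0576) and Ptger3 with thinned cells (-0.75, 0.0846). Cells with counts of both Birc5 and Mki67 were 2 of 804 DCT cells in vehicle libraries and 27 of 1097 in furosemide libraries, a mean of 0.292% ± 0.255 and 2.48% ± 0.954 (SD, n = 3; exact two-sided permutation p = 0.1, the smallest possible, adjusted p = 0.5). Furosemide libraries 2, 4 and 6 had 1.49%, 2.58% and 3.39%, and vehicle libraries 1, 3 and 5 had 0, 0.405% and 0.472%. Thinned to a fixed depth, 0 and 12 cells held both, a mean of 1.14% with furosemide (exact permutation p = 0.1). In CNT the cells were 0 of 400 with vehicle, which allows a share of up to 0.75%, and 12 of 716 with furosemide (exact permutation p = 0.1; thinned, exact permutation p = 0.4). In TAL they were 0 of 2624, which allows up to 0.114%, and 4 of 1498. Median counts per DCT cell were 1318 with vehicle and 1334 with furosemide. Cells with both were 1 of 1523 with vehicle and 0 of 1443 with furosemide in Proximal s1/s2, where the 0 allows up to 0.208%. They were 2 of 1460 and 3 of 1313 in Proximal s1/s2/s3, and 3 of 1915 and 4 of 2560 in Proximal s2/s3. They were 3 of 541 and 7 of 684 in CCD principal, 0 of 160 and 3 of 325 in DCT2, and 4 of 297 and 4 of 249 in Immune cells (means of 1.19% and 1.38%). In DCT2 the 0 allows up to 1.88%, above the furosemide mean of 0.935%.

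**Figure D2:**
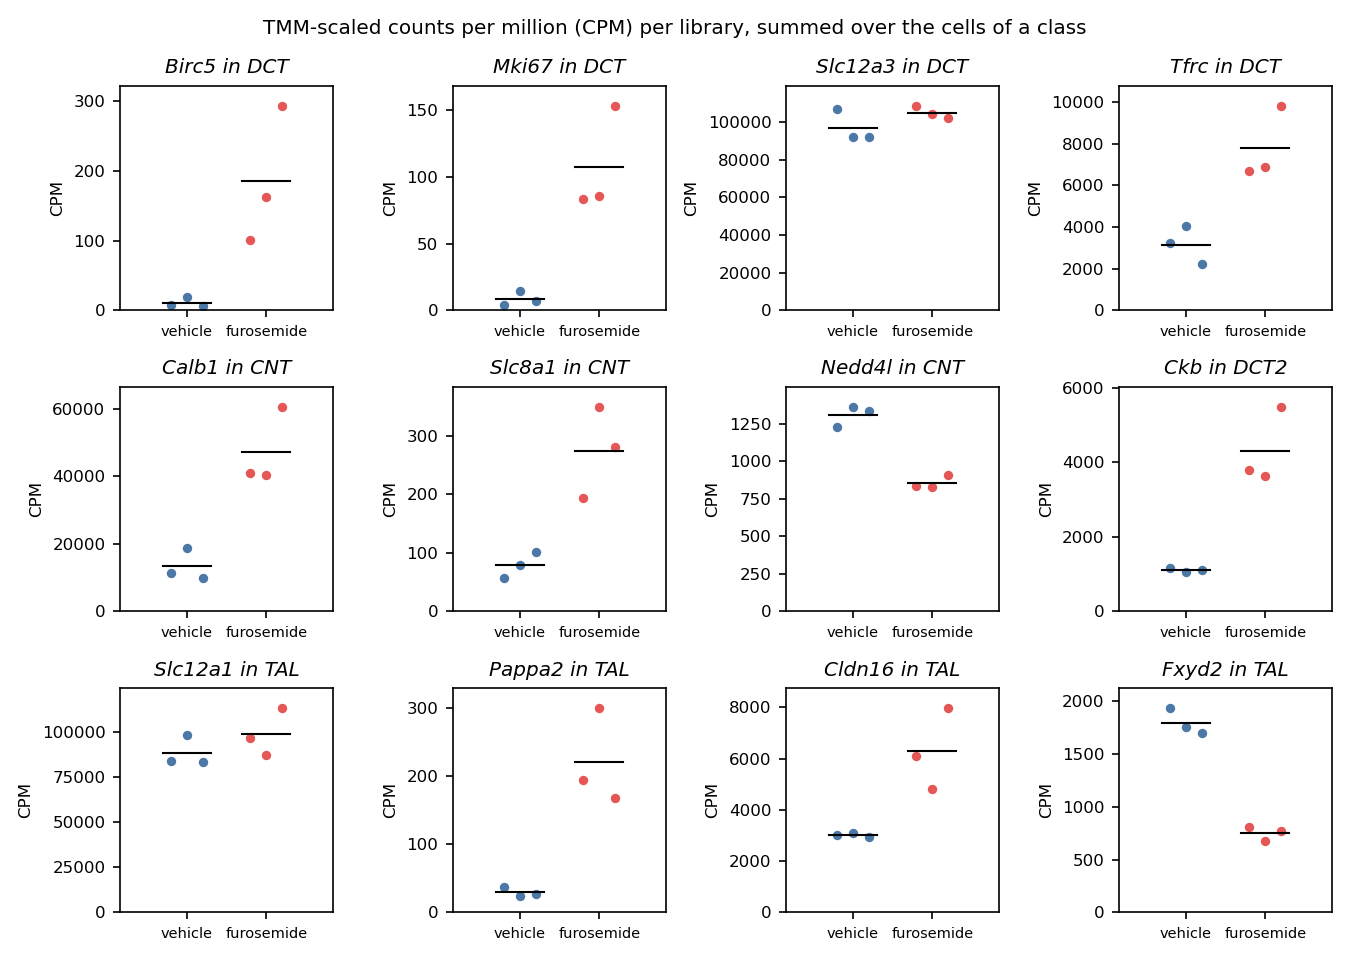
TMM-scaled counts (CPM, vertical axes, 1 panel per gene and class) in each library, vehicle and furosemide side by side, with points for libraries and group means. Birc5, Mki67 and Tfrc in DCT, Calb1 in CNT, Ckb in DCT2 and Pappa2 in TAL lay higher in all furosemide libraries, Fxyd2 in TAL and Nedd4l in CNT lay lower, and Slc12a3 in DCT and Slc12a1 in TAL did not pass.

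In DCT2 cells, 3 of 211 genes passed, each higher with furosemide. Creatine kinase Ckb rose from 1119 ± 54.7 to 4303 ± 1023 CPM (log2 change 1.94 ± 0.19, adjusted p = 0.000177), Tfrc from 880.5 ± 259.6 to 2964 ± 681 CPM (1.75 ± 0.24, adjusted p = 0.00207) and the glutathione peroxidase Gpx6 from 844 ± 186 to 2408 ± 713 CPM (1.52 ± 0.25, adjusted p = 0.00652). Calb1, at its highest level here, did not pass (0.03 ± 0.17, adjusted p = 0.942) and turned to -0.07 without furosemide library 6. None of 17 genes of DCT salt transport passed, also none adjusted over the list alone (camera adjusted p = 0.813), and none of 9 of calcium and magnesium handling (0.852). Gpx6 did not pass with equal cell numbers (1.07, adjusted p = 0.194). Without vehicle library 1 and without furosemide library 6, 5 genes passed each.

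In CNT cells, 13 of 256 genes passed, 6 higher and 7 lower with furosemide. Calb1, which buffers calcium in this segment, rose from 13335 ± 4704 to 47303 ± 11397 CPM (log2 change 1.82 ± 0.27, adjusted p = 0.0122), and the sodium-calcium exchanger Slc8a1 from 79.4 ± 22.8 to 274.9 ± 77.3 CPM (1.80 ± 0.31, adjusted p = 0.0157). Nedd4l, a ubiquitin ligase of the epithelial sodium channel, fell from 1306 ± 70.9 to 857 ± 43.9 CPM (-0.61 ± 0.13, adjusted p = 0.0389), and the sodium pump regulator Fxyd4 fell too (-0.71 ± 0.15, adjusted p = 0.0389). Tfrc rose (1.82 ± 0.30, adjusted p = 0.0122), as did clusterin, Clu (0.80 ± 0.19, 0.0427), and Cd8a (1.15 ± 0.19, 0.0122), which is known from T cells and was the leading gene of CNT here. Slc8a1 and Clu were also among the 10 leading CNT genes. Slc12a3 rose (2.27 ± 0.36, adjusted p = 0.0122) at 0.214% of its DCT level, and Slc12a1 fell (-1.52 ± 0.33, 0.0389) at 0.137% of its TAL level. Adamts1 (-1.13 ± 0.21, adjusted p = 0.0226), Sphk1 (-0.92 ± 0.20, 0.0389) and the growth factor Hbegf (-0.62 ± 0.15, 0.0433) fell, and so did Smad7 (-0.69), chosen after its value was seen.

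Of 10 CNT genes of calcium and magnesium handling, Calb1 and Slc8a1 rose, with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.177). Of 17 genes of DCT salt transport, Calb1 and Slc12a3 rose, also 2 adjusted over the list alone (0.177). Of 13 genes of sodium channel and aldosterone signalling, Nedd4l and Fxyd4 fell, also 2 adjusted over the list alone (0.822; median 0.01, mean -0.05). None of 13 IGF genes passed (0.985). Slc12a3 in CNT did not pass with equal cell numbers (1.21, adjusted p = 0.205), in the second clustering (0.76, 0.694) or with cells thinned to a fixed total (1.51, 0.0884), and Slc12a1 did not when thinned (-0.93, 0.249) or with equal cell numbers (-1.57, 0.0906). Equal cell numbers also ended the calls of Hbegf (-0.55, adjusted p = 0.0834) and Sphk1 (-0.90, 0.127), library size alone those of Clu (0.63, 0.0769) and Sphk1 (-1.06, 0.0581), and leaving out the top 5% of totals those of Clu (0.79, 0.0512) and Hbegf (-0.57, 0.0856). With thinned cells Cd8a (0.91, adjusted p = 0.0921), Clu (0.82, 0.064), Fxyd4 (-0.69, 0.0884), Hbegf (-0.57, 0.113), Nedd4l (-0.52, 0.122) and Sphk1 (-1.03, 0.0884) did not pass. No CNT gene passed edgeR's test without vehicle library 1 (Calb1 1.74, adjusted p = 0.141; Slc8a1 1.63, 0.146) or without furosemide library 4 (Calb1 1.93, 0.0532; Slc8a1 1.58, 0.0819). Counts were 3 and 5 without vehicle libraries 3 and 5, and 8 each without furosemide libraries 2 and 6. Nedd4l did not pass without any of the 6, with log2 changes of -0.63, -0.58 and -0.58 without vehicle libraries 1, 3 and 5 and -0.61, -0.58 and -0.70 without furosemide libraries 2, 4 and 6. Clu, Hbegf and Sphk1 did not pass without any of the 6 either, Adamts1, Fxyd4 and Slc12a1 missed the threshold without 5 of them, Cd8a without 4, and Tfrc, Slc8a1 and Slc12a3 without 3. Without a filter on low counts, Nedd4l (adjusted p = 0.0551), Adamts1 (0.0536), Fxyd4, Slc12a1, Hbegf and Clu (0.0551 each) and Sphk1 (0.0536) did not pass either, which left 5 higher and 0 lower.

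In CCD principal cells, none of 281 genes passed edgeR's test, with 53 at an unadjusted p under 0.05, while 18 passed with DESeq2 and 0 with limma-voom. The plasminogen activator Plat (log2 change 3.77 ± 0.62, adjusted p = 0.0618), Calb1 (1.26 ± 0.23, 0.0618) and Kl, the klotho gene (1.34 ± 0.28, 0.0937), had the smallest p among higher genes, with Plat at 0.271% of its highest class, and Ctgf (-0.97 ± 0.18, 0.0618), Slc12a1 (-1.55 ± 0.36, 0.0937) and Slc2a1 (-0.62 ± 0.14, 0.0937) among lower ones. The sodium channel subunits Scnn1b (0.18 ± 0.18) and Scnn1g (0.38 ± 0.13, adjusted p = 0.208) did not pass, nor did any of 13 genes of their list (camera adjusted p = 0.25). Of 7 genes of calcium and magnesium handling none passed over all genes and 3 were higher adjusted over the list alone (median 0.79, camera adjusted p = 0.147). Without furosemide library 6, 3 genes passed.

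In the 3 proximal classes no gene passed edgeR's test. The genes tested, those at an unadjusted p under 0.05 and those passing with DESeq2 were 273, 14 and 1 in Proximal s1/s2, 280, 20 and 2 in Proximal s1/s2/s3, and 291, 21 and 3 in Proximal s2/s3, with 0 each by limma-voom. Calb1 had the smallest p in each (1.54 ± 0.25, 2.51 ± 0.38 and 1.51 ± 0.22, adjusted p = 0.153, 0.0767 and 0.055). In Proximal s1/s2, Clu (1.05), Ifrd1 (0.88), Igfbp5 (-0.52 ± 0.13), Slc12a1 (-0.64) and Kap (-1.15 ± 0.33) followed. In Proximal s1/s2/s3 these were Trf (0.94), G6pc (0.47 ± 0.17), Hspa1a (-1.46 ± 0.36), Igfbp5 (-0.62 ± 0.18) and Slc12a1 (-0.72), and in Proximal s2/s3 Cdkn1a (0.84 ± 0.16, adjusted p = 0.14), Slc12a3 (0.71), Hspa1a (-1.79 ± 0.45), Slc12a1 (-1.07) and Acta2 (-3.39 ± 1.00; 172 counts in vehicle library 1 and 4 to 16 in the others). Besides Calb1 and Slc12a1, several of these stood at under 1% of their highest class, namely Clu in Proximal s1/s2 (0.283%) and Cdkn1a (0.506%), Slc12a3 (0.108%), Hspa1a (0.996%) and Acta2 (0.0747%) in Proximal s2/s3, and are not read as expression of the class. Igf1r (-0.26 ± 0.17, adjusted p = 0.799) and Igfbp1 (0.70 ± 0.21, 0.459), both at their highest level in Proximal s1/s2, did not pass. In the 3 classes summed, 1 of 335 genes passed, Calb1 (1.83 ± 0.22, adjusted p = 0.033), from 34.9 ± 6.64 to 124 ± 24.0 CPM. Of 18 IGF genes none passed and 1 was lower adjusted over the list alone (camera adjusted p = 0.147), of 12 genes of proximal sodium and solute transport none passed (0.985; median -0.05, mean 0.04), of 7 of calcium and magnesium handling Calb1 rose (0.655; median -0.36, mean 0.15), and none of 10 injury genes (0.147) or 6 androgen-responsive genes (0.354) passed. Calb1 did not pass in the sum without vehicle libraries 3 (1.75, adjusted p = 0.204) and 5 (1.77, 0.0751) or furosemide libraries 4 (1.84, 0.194) and 6 (1.69, 0.117), or with thinned cells (1.76, 0.06).

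Calb1 and Slc12a1 also changed in classes that hold little of them, Calb1 in TAL and Podocytes/Glom and Slc12a1 in DCT and CNT. The share of cells with a Calb1 count was 4.60% with vehicle and 11.7% with furosemide in TAL, 4.12% and 9.52% in Immune cells, and 4.40% and 9.38% in Proximal s1/s2. In DCT2 cells, Calb1 stood at 72118 plain CPM with vehicle and 80214 with furosemide, and in DCT cells at 26181 and 41848. The share with an Slc12a1 count was 15% and 7.73% in Proximal s2/s3 and 21.5% and 10.9% in CNT. In these classes the values of both genes are not read as expression of the class. Over all cells, Calb1 rose by 1.57 ± 0.21.

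**Figure D3:**
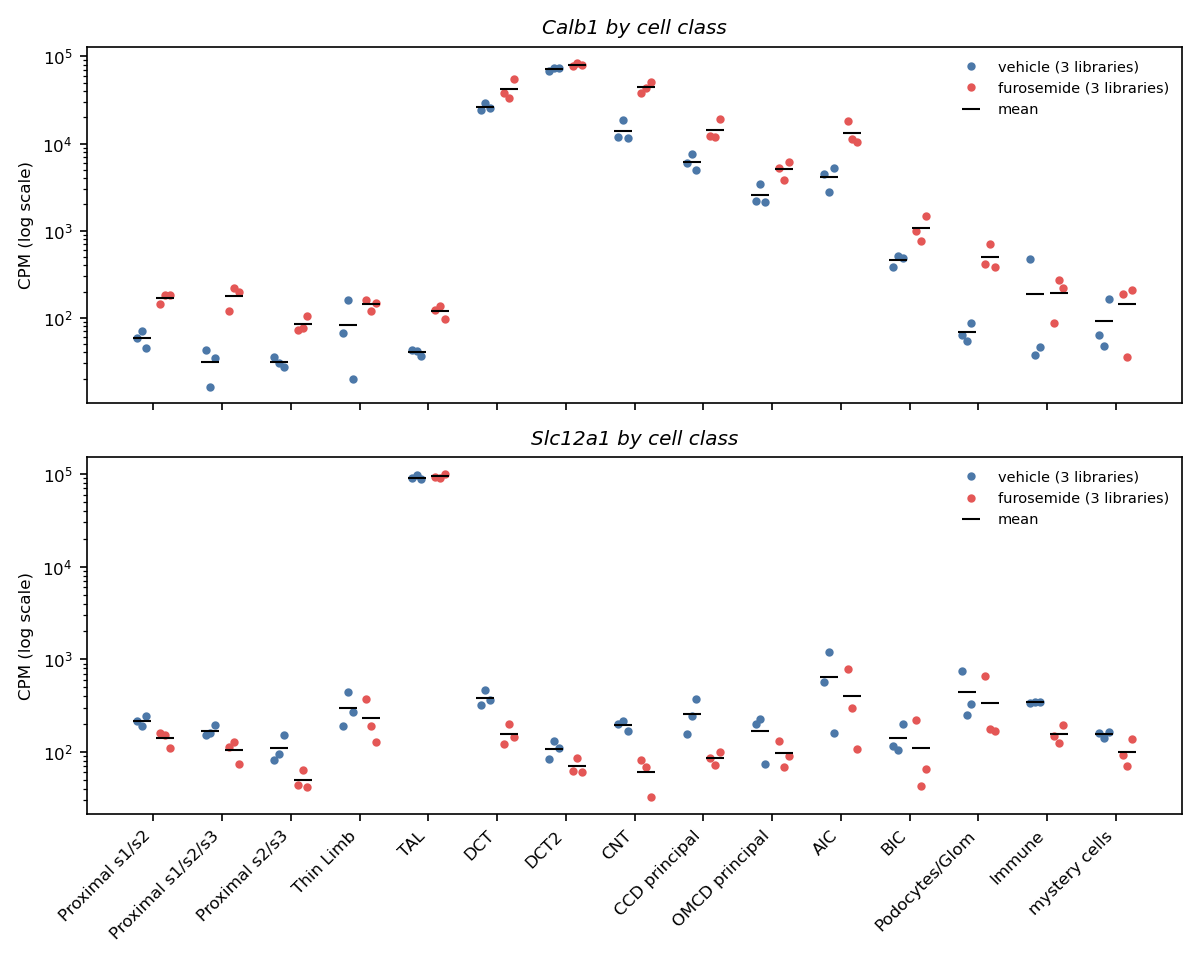
Plain CPM of Calb1 and Slc12a1 (vertical log axes) in each class, with a point per library and a dash at each group mean. Calb1 stood highest in DCT2 (72118 and 80214) and Slc12a1 in TAL, and among classes that hold far less of them Calb1 rose in TAL and Slc12a1 fell in DCT and CNT.

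In Thin Limb cells, 5 of 266 genes passed. The amino acid transporter gene Slc7a12 (3.97 ± 0.56, adjusted p = 0.024; 2 to 5 counts per vehicle library) and Clu (1.32 ± 0.20, 0.024) rose, and histone Hist1h1c (-1.49 ± 0.22, 0.024), Ppp1r1a (-2.01 ± 0.33, 0.0243) and Fxyd2 (-3.76 ± 0.63, 0.0243; 0 to 3 counts per furosemide library) fell. Slc7a12 was among the 10 leading genes of the class. Ppp1r1a and Fxyd2 stood at 2.92% and 2.46% of their highest class. Clu, at its highest level in DCT2, also stood at under 5% of it. Only 2 of the 5 called genes, Slc7a12 and Hist1h1c, lay above that bound, both at their highest level here. Of 11 genes of TAL salt transport 1 fell (Ppp1r1a), also 1 adjusted over the list alone, and camera placed the list lower (median -0.67, adjusted p = 0.0493), but not with an estimated correlation (adjusted p = 0.753). Counts were 0, 0 and 1 without vehicle libraries 1, 3 and 5, and 5, 0 and 5 without furosemide libraries 2, 4 and 6, so that Clu, for example, was 1.44 (adjusted p = 0.0685) without vehicle library 1, 1.22 (0.0764) without vehicle library 3, 1.44 (0.186) without vehicle library 5 and 1.52 (0.124) without furosemide library 4. With equal cell numbers Ppp1r1a (-1.84, adjusted p = 0.12) and Slc7a12 (4.03, 0.12) did not pass, without a filter Ppp1r1a (-1.90, 0.0507) and Fxyd2 (-3.66, 0.0833), in the second clustering Ppp1r1a (-1.47, 0.0539) and with thinned cells Clu (1.0, 0.102).

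In BIC cells, 1 of 245 genes passed: Timp3, an inhibitor of metalloproteinases, fell from 789 ± 58.7 to 259 ± 46.9 CPM (-1.60 ± 0.19, adjusted p = 0.00416), and it passed without each of the 6 libraries. The count of BIC genes was 6 without furosemide library 4 and 2 without vehicle library 5. Pendrin, Slc26a4 (0.15 ± 0.09, adjusted p = 0.562), and Igfbp5 (0.15 ± 0.16) did not pass. Among mystery cells, a class of 107 cells led by Wnt4 and Wnt9b, Hsd11b2 (1.99 ± 0.33), Scnn1g (1.68 ± 0.31) and Lcn2 (1.51 ± 0.29) rose among 131 genes (adjusted p = 0.0448 each). In the second clustering all 107 fell in a cluster that the authors named mixed. Whether the makeup of this class changed was not tested. Hsd11b2 and Scnn1g, known from principal cells, stood at 6.96% and 9.47% of their highest class. The count there was 0, 1 and 0 without vehicle libraries 1, 3 and 5, 1, 0 and 7 without furosemide libraries 2, 4 and 6, and 0 with library size alone. Scnn1g missed the threshold in 10 of 13 settings, among them DESeq2 (1.70, adjusted p = 0.0517), limma-voom (1.56, 0.0706), equal cell numbers (1.75, 0.118) and no filter (1.72, 0.0812), and Lcn2 missed it in 7 of 14, among them equal cell numbers (1.31, 0.118). In Podocytes/Glom, only Calb1 passed among 239 genes (2.81 ± 0.38, adjusted p = 0.0348), at 0.373% of its highest class, and it did not pass without any library (2.59, adjusted p = 0.231, without furosemide library 4 to 3.08, 0.145, without vehicle library 5) or without the top 5% of totals (2.11, adjusted p = 0.643), with equal cell numbers (3.01, 0.116) or without a filter (2.79, 0.0672). There camera placed the 5 tested genes of calcium and magnesium handling higher (adjusted p = 0.0267, but 0.753 with an estimated correlation), with 1 rising over all genes and 2 adjusted over the list alone. All 5 stood at under 1% of their highest class there, such as S100g at 0.484% and Kl at 0.985%.

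No gene passed edgeR's test in OMCD principal (244 tested, 31 at an unadjusted p under 0.05, 6 with DESeq2, 0 with limma-voom), AIC (219, 13, 1 and 0) or Immune cells (196, 11, 1 and 0). Without vehicle library 1 and without furosemide library 6, 2 genes passed each in OMCD principal, and 1 each in Immune cells without vehicle library 3 and furosemide library 6. The smallest adjusted p was that of H2-Aa in OMCD principal (0.0567), a gene of antigen-presenting cells at 0.292% of its highest class, with 27, 124 and 146 counts in vehicle libraries 1, 3 and 5 and 1, 0 and 0 in furosemide libraries 2, 4 and 6. It was that of Calb1 in AIC (1.86 ± 0.34, 0.177) and of the chemokine Ccl17 in Immune cells (5.64 ± 1.22, 0.313), which had 201 and 383 counts in furosemide libraries 2 and 4 and 7 in library 6. The anion exchanger Slc4a1 in AIC did not pass (-0.41 ± 0.28). In Immune cells, camera placed 5 genes of TAL salt transport lower (adjusted p = 0.000735, but 0.753 with an estimated correlation), of which none passed over all genes and 3 were lower adjusted over the list alone. All of these but Wnk1 stood at under 1% of their highest class there, with Umod at 0.267%, Egf at 0.205%, Ppp1r1a at 0.396% and Slc12a1 at 0.269%. That list and the lists called in Thin Limb and Podocytes/Glom were the 3 that passed, and none passed with an estimated correlation (adjusted p = 0.753 each). With fry their adjusted p was 0.0516 in Immune cells, 0.124 in Thin Limb and 0.242 in Podocytes/Glom. The Thin Limb list did not pass without vehicle libraries 3 (0.0683) and 5 (0.0577) or furosemide library 6 (0.0765), nor the Podocytes/Glom list without vehicle library 5 (0.103) or furosemide library 2 (0.193). The Immune list passed without each library.

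**Figure D4:**
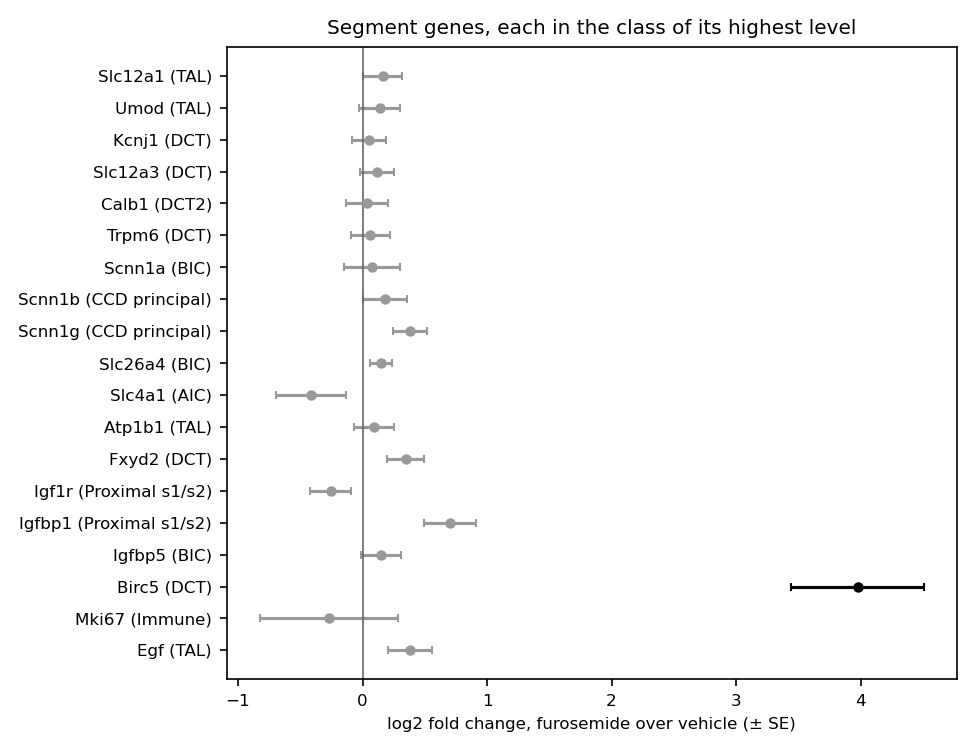
Log2 fold change of furosemide over vehicle (horizontal axis, with bars of 1 SE, n = 3 against 3 libraries) of core genes that could be tested, each in its class of highest level. Birc5 in DCT, at 3.98, is drawn in black as the gene of this set that passed edgeR's test, and Slc12a3 in DCT (0.11) and Slc12a1 in TAL (0.16) lay near 0.

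Of the 24 core genes, Birc5 alone passed edgeR's test in its class of highest level. The set was written knowing that the study reports on Birc5, so this is not an independent finding. Kcnj1 (0.05 ± 0.14) and Trpm6 (0.06 ± 0.16) in DCT, Scnn1a in BIC (0.07 ± 0.22), Atp1b1 in TAL (0.09 ± 0.16) and Mki67 in Immune cells (-0.27 ± 0.55) did not pass, and each of these 5 turned direction without at least 1 library. Atp1b1 and Kcnj1 did so without vehicle library 1 (-0.0048 and -0.0461), Scnn1a without furosemide library 4 (-0.18) and vehicle library 3 (-0.05), and Mki67 without vehicle library 3 (0.22). Trpm6 did so without furosemide library 2 (-9e-04) and vehicle libraries 1 (-0.0153) and 5 (-0.0091), and Umod in TAL without vehicle library 1 (-0.02). Pvalb (9 counts over all cells), Slc9a3 (49 counts) and Aqp2 (27 counts with vehicle and 23 with furosemide in its highest class, mystery cells) had too few counts for a test there.

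The whole libraries mix expression with the makeup of cells, and 19 of their 426 tested genes passed, 8 higher and 11 lower. The genes of calcium transport Calb1 (1.57 ± 0.21, adjusted p = 0.0239), Trpv5 (1.17 ± 0.17, 0.0239) and Slc8a1 (1.90 ± 0.32, 0.0264) rose, as did Cd8a (2.06 ± 0.30, 0.0239), Clu (0.88 ± 0.14, 0.0247), Mki67 (1.79 ± 0.30, 0.0264), Birc5 (1.54 ± 0.31, 0.049) and Pappa2 (2.04 ± 0.42, 0.049). Ptgds (-1.51 ± 0.17, 0.0239), Lypd2 (-2.57 ± 0.32, 0.0239), Gpx6 (-0.998 ± 0.15, 0.024), Pdgfb (-0.75 ± 0.12, 0.024) and the calcium-sensing receptor Casr (-0.85 ± 0.15, 0.0351) fell, and Hist1h1c, Fst, Nr0b2, Nupr1 and Cldn10, chosen after their values were seen, fell as well. Of 17 genes of TAL salt transport 3 fell, and 7 adjusted over the list alone (camera adjusted p = 0.0623), next to the lower share of TAL cells (13.3% against 23.7%). Of 10 genes of calcium and magnesium handling 3 rose and 1 fell, against 6 and 3 adjusted over the list alone (0.147). Of 5 cell-cycle genes Birc5 and Mki67 rose, against 2 higher and 1 lower over the list alone (0.271), and of 20 IGF genes Pappa2 rose (0.658). Counts were 0, 0 and 5 without vehicle libraries 1, 3 and 5, and 2, 0 and 13 without furosemide libraries 2, 4 and 6. Calb1, for example, was 1.67 (adjusted p = 0.0856) without vehicle library 1, 1.66 (0.0829) without vehicle library 3, 1.56 (0.0569) without furosemide library 2 and 1.70 (0.0592) without furosemide library 4. Birc5 and Pappa2 each missed the threshold in 10 of 12 settings, namely without each of the 6 libraries and with limma-voom (1.51, adjusted p = 0.059, and 2.0, 0.0838), library size alone (1.45, 0.0532, and 1.97, 0.0603), no filter (1.54, 0.0534, and 2.03, 0.0511) and thinned cells (1.44, 0.076, and 2.09, 0.129). Mki67, Casr and Pdgfb also missed it without each of the 6 libraries, and with thinned cells so did Casr (-0.91, 0.0726), Cd8a (1.60, 0.0726) and Pdgfb (-0.61, 0.0731).

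The last question was which effects differed between the proximal tubule and later segments. In TAL against the summed proximal classes, 5 of 362 genes differed, 1 more positive and 4 more negative in TAL. Fxyd2 differed by -1.24 ± 0.16 (adjusted p = 0.0124; -1.26 in TAL and -0.09 in proximal cells), G6pc by -2.21 ± 0.31 (0.0136; -1.80 and 0.35) and Tfrc by -1.39 ± 0.23 (0.0296; -0.70 and 0.58). Mgp differed by -5.48 ± 0.63 and the chemokine Ccl5 by 3.87 ± 0.49 (adjusted p = 0.0124 each). The Mgp value rests on furosemide libraries 2 and 4, with 591.7 and 200.0 plain CPM in Proximal s2/s3, and that of Ccl5 on vehicle library 1 (95.2 in Proximal s2/s3) and vehicle library 3 (55.6 in Proximal s1/s2/s3). Mgp stood at 0.0256% of its highest class in TAL and 0.244% in Proximal s2/s3, and Fxyd2 at 0.719% in Proximal s2/s3. Such low levels are not read as expression of those classes. G6pc in TAL also stood far below its proximal level. In DCT, 1 of 353 genes differed, Birc5, by 4.52 ± 0.62 (adjusted p = 0.0394; 3.98 and -0.47). In CNT none of 355 and in CCD principal none of 371 genes differed by edgeR's test, with 37 and 43 at an unadjusted p under 0.05, and 0 each with limma on differences per library (DESeq2 was not run on differences). With that limma test no gene passed in TAL or DCT either (Birc5 4.37, adjusted p = 0.0607; Fxyd2 -1.24, G6pc -2.19, Mgp -4.67 and Ccl5 3.46, 0.0537 each; Tfrc -1.39, 0.0789).

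For TAL the counts of differences were 5, 2 and 9 without vehicle libraries 1, 3 and 5, and 5, 1 and 13 without furosemide libraries 2, 4 and 6. Fxyd2 did not pass without furosemide library 4 (-1.16, adjusted p = 0.0598) and vehicle library 3 (-1.22, 0.06), G6pc without vehicle library 3 (-2.28, 0.06), and Mgp (-5.02) and Ccl5 (3.53) without furosemide library 4 (0.0598 each). Tfrc did not pass without furosemide library 4 (-1.23, 0.0866) and vehicle libraries 3 (-1.37, 0.133) and 5 (-1.27, 0.0678). Birc5 in DCT did not pass without furosemide libraries 2 (4.93, 0.12) and 6 (4.88, 0.0774) or vehicle libraries 1 (4.35, 0.102) and 5 (4.47, 0.173). In DCT 3 genes differed without furosemide library 4, in CNT 3 without vehicle library 3 and 1 without furosemide library 6, and in CCD principal 2 without vehicle library 5 and 1 without furosemide library 6.

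Genes whose 3 furosemide libraries did not overlap with the 3 vehicle libraries made up 23.7% of those tested in TAL, 19.6% in DCT, 19% in DCT2, 27.3% in CNT, 23.5% in CCD principal, 20.8% in BIC, 20.3% in Thin Limb, 16.8% in mystery cells, 16.4% in OMCD principal, 13.7% in AIC, 10.7% in Immune, 10% in Podocytes/Glom and 10 to 11% in the proximal classes, where chance gives 10%. On GRCm38, Slc12a1 lies on chromosome 2 (125152505 to 125230002), Slc12a3 on 8 (94329201 to 94366214), Calb1 on 4 (15881264 to 15908064), Pappa2 on 1 (158711727 to 158980490) and Fxyd2 on 9 (45399669 to 45410278). Cldn16 lies on chromosome 16 (26463135 to 26482765), Tfrc on 16 (32608920 to 32632794), Birc5 on 11 (117849251 to 117855743) and Mki67 on 7 (135689784 to 135716361), each annotated as protein-coding.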

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

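The 6 results here stood out because the test of the difference between a segment and the proximal tubule passed. The tests on Calb1 within cells and on cells mixed into single classes, on free RNA in TAL and on cells with both transcripts in DCT were chosen only after the results were seen, and so was the reading of each test by its 95% interval. In TAL against the summed proximal classes, the difference of log2 changes was -1.24 for Fxyd2, -2.21 for G6pc, -1.39 for Tfrc, -5.48 for Mgp and 3.87 for Ccl5. The Mgp value rests on furosemide libraries 2 and 4, with 838 and 468 counts in Proximal s2/s3 against 1 to 27 in the others. The Ccl5 value rests on vehicle library 1, with 155 counts in Proximal s2/s3, and on vehicle library 3, with 52 in Proximal s1/s2/s3. Mgp in TAL and in Proximal s2/s3, and Fxyd2 in Proximal s2/s3, stood at under 1% of their highest class. In DCT against the proximal classes, the difference was 4.52 for Birc5.

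The first pattern is the higher Calb1 and lower Slc12a1 in classes that hold each at under 1% of its highest class. Free RNA that follows the makeup of all cells would give a slope of 1 between a class's log2 changes and those over all cells, if the latter held no error. Error in the changes over all cells can lower this slope. Over 126 such genes the slope was 0.557 (95% interval 0.369 to 0.818). Free RNA may thus account for a part of the pattern, and a slope under 1 cannot tell a part from all of it. Cells of other classes, mixed in as doublets or by assignment, would put most Calb1 counts into cells with 10 or more. Over all these classes together such cells held 19.4% (10.3 to 28.6). This argues against mixed-in cells as the main source of the Calb1 counts of the whole, and Slc12a1 was not tested in this way. Mixed-in cells stay open in Podocytes/Glom (44.5%, 0 to 72.6, from 2 cells), Immune cells (46.3%, 0 to 71.9) and Proximal s1/s2/s3 (37.0%, 3.44 to 59.3), and in Podocytes/Glom Calb1 did not pass without the top 5% of totals (2.11, adjusted p = 0.643). A change of Calb1 within these cells should differ from that over all cells, and the median difference was -0.16 standard errors (95% interval of the median -1.38 to 2.45, single classes from -1.55 in Thin Limb to 3.30 in Podocytes/Glom), which leaves it open.

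The second pattern is the 15 genes called in TAL. If a changed mix of Cldn16 and Cldn10 cells were the cause, the changes should vanish inside either kind, and the median ratio of changes inside Cldn10-only cells to those of the class was 0.96 (0.829 to 1.55), and inside Cldn16-only cells 1.03 (0.617 to 1.42), where Fxyd2 turned from -1.26 to 0.53 ± 0.28 and Calb1 was 0.85 ± 0.44 against 1.66. This decides nothing and leaves the mix open, because cells were sorted by Cldn16, itself among the called genes, and the share of Cldn10-only cells fell from 32.5% to 14.2%. Free RNA may explain genes at low level, yet 13 of the 15 stood at 5% or more of their highest class. The others were Calb1 and G6pc. G6pc had a log2 change of 0.43 over all cells and of -1.80 in TAL. Free RNA that follows all cells would not give this fall, which leaves Calb1. For cell totals, the ratio of changes after thinning was 1.096 (1.06 to 1.13). The sums were already scaled to their totals, so thinning could hardly lower this ratio and decides little. Median counts per TAL cell were 1485 with vehicle and 1531 with furosemide.

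The third pattern is the higher Birc5 and Mki67 in DCT. Free RNA that hits cells independently would give 1.88 furosemide cells with both transcripts, and 27 were seen, a ratio of 14.4 (9.48 to 20.9), which argues against it. Doublets with other cells may raise both. Without cells in the top 5% of totals the change of Birc5 was 1.24 times as large (0.92 to 1.55). Before that removal, DCT cells of vehicle libraries 1, 3 and 5 held only 4, 8 and 2 Birc5 counts. Losing a few of these can raise the ratio, and its interval leaves out the error of the full value. The ratio thus does not decide on doublets. Deeper furosemide cells are argued against by the difference after thinning, 1.14 percentage points. A larger number of cycling DCT cells remains a candidate, and doublets of DCT cells with cycling cells of a like total were not tested.

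The 10 splits of the 6 libraries into 3 and 3 cannot give a share under 0.05. The real split gave 15 called genes in TAL, 13 in DCT, 13 in CNT, 19 over all cells, 5 in Thin Limb, 3 in DCT2, 3 in mystery cells, and 1 each in BIC, Podocytes/Glom and the summed proximal classes, and the highest of the other splits gave 3, 1, 0, 0, 0, 0, 0, 0, 0 and 0. In each of these 10 sums 1 split, the real one, gave as many. In classes with a real count of 0 all 10 splits gave as many, and the highest other count was 1 in Proximal s1/s2, 0 in Proximal s1/s2/s3, 5 in Proximal s2/s3, 1 in CCD principal, 0 in OMCD principal, 0 in AIC and 12 in Immune cells. The 12 came from libraries 1, 4 and 6 against the others, which may reflect a structure of the samples in that class and was not tested. For differences from proximal cells the real and highest other counts were 5 and 1 in TAL (1 split as high), 1 and 1 in DCT (2 splits), 0 and 1 in CNT (10 splits) and 0 and 2 in CCD principal (10 splits). For gene lists they were 3 and 14, with 7 of 10 splits as high, the real one among them. Camera at its preset correlation thus often passed as many lists under other splits, and the 3 passing lists do not stand out. The 14 came from libraries 1, 5 and 6 against the others, and what lies behind them was not tested.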

How the results depend on the processing

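Of 70 called genes and differences that are named, none turned direction under any alternative, and 6 passed under all of them. Genes that the rule named because their libraries did not overlap between treatments could hardly turn when a library was left out. For them the stable direction was largely fixed by the naming rule and is no separate support. Leaving out a library leaves 2 against 3, with fewer samples for each test, although some counts rose. Of 384 such fits of the 64 called genes in classes, 240 (62.5%) lost the call, and of 521 other fits 67 (12.9%) did. Among the 61 uncalled genes, 3 of 366 fits without a library and 27 of 496 others gained a call. For the 6 called segment differences, 12 of 36 fits without a library and 6 of 18 others lost it, and for the 34 uncalled ones 8 of 204 and 2 of 102 gained it. For these the cause was not tested unless said. No paired analysis was possible because the libraries carry no replicate number, so the planned replicate blocks were not run. The planned pseudocount and low-value filter for normalized values were not run because the table holds counts. DESeq2 called all 15 TAL, 13 DCT, 13 CNT and 19 whole-library genes and more. With library size alone, the median change of all genes moved to 0.236 in Thin Limb, -0.159 in CNT, -0.169 in AIC, 0.145 in DCT2, -0.111 in TAL, 0.104 in Immune and -0.101 in the summed proximal classes, and changes under that setting are relative to it.

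Counts of called genes that moved by over 1.5 times were, with DESeq2, 43 over all cells, 32 in TAL, 24 in CNT, 22 in DCT, 18 in CCD principal, 15 in Thin Limb, 12 in BIC, 6 in OMCD principal, 5 in the proximal sum, 3, 2 and 1 in Proximal s2/s3, s1/s2/s3 and s1/s2, and 1 each in AIC and Immune. Without a filter they were 5 in CNT, 4 in BIC, 3 in Thin Limb, 1 each in CCD principal, Proximal s1/s2/s3 and Proximal s2/s3, and 0 in Podocytes/Glom, where more genes are tested. With library size alone they were 5 in DCT2, 1 in OMCD principal and 0 in mystery cells, and with RLE 1 in OMCD principal. With equal cells they were 3 in Thin Limb, 2 in BIC, 1 in mystery cells and 0 in Podocytes/Glom, and without the top 5% of totals 2 in CCD principal and 0 in Podocytes/Glom. Among alternatives chosen after seeing the data, thinned cells gave 28 in TAL, 5 in DCT2, 4 in CNT, 3 in BIC, 3 in Thin Limb, 1 in AIC and 0 in Podocytes/Glom and the proximal sum, the second clustering 2 in BIC, and leaving out genes under 5% of their highest class 2 in Thin Limb and 0 in Podocytes/Glom. The second clustering was run only for TAL, DCT, CNT, BIC, Thin Limb, AIC and CCD principal. Other classes were left out, although some, such as Podocytes/Glom, had a close counterpart. Its DCT also took in the cluster DCT sub3, with 452 DCT2 cells. Its AIC took in OMCD principal cells, 241 in the cluster AIC and 132 in AIC sub2. For DCT and AIC it is thus not a repeat on the same class. For segment differences, limma gave 0 in TAL and 0 in DCT, and no filter 2 in DCT. With an estimated correlation 0 lists passed (adjusted p = 0.753 for each of the 3), and with fry 0 (0.0516 in Immune, 0.124 in Thin Limb, 0.242 in Podocytes/Glom). The edgeR test of cell numbers called CNT (0.82), DCT2 (1.06) and TAL (-0.84).

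Directions turned for Atp1b1 in TAL (-0.0177), Kcnj1 in DCT (-0.0438) and Trpm6 in DCT (-0.0346) with library size alone, Kcnj1 in DCT in the second clustering (-0.004), and Scnn1a in BIC with thinned cells (-0.0781), none of them called. Shares without TAL turned in AIC (-0.0033) and Podocytes/Glom (-0.12). Cell-cycle cells turned, in percentage points, in OMCD principal (-0.57), Proximal s2/s3 (-0.666) and mystery cells (-0.397) with 1 or more transcripts, and in Immune (-0.223) and Proximal s2/s3 (-0.0568) when thinned.

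Leaving out each library in turn gave these lowest and highest values. Called genes were 3 to 21 in TAL, 0 to 11 in DCT, 3 to 5 in DCT2, 0 to 8 in CNT, 0 to 5 in Thin Limb, 1 to 6 in BIC, 0 to 3 in CCD principal, 0 to 2 in OMCD principal, 0 to 1 in Immune and in the proximal sum, 0 to 7 in mystery cells, 0 to 13 over all cells, and 0 in AIC, Podocytes/Glom and each proximal class. Segment differences were 1 to 13 in TAL, 0 to 3 in DCT, 0 to 3 in CNT and 0 to 2 in CCD principal. Lists passing were 2 to 10, with adjusted p of 0.00215 to 0.0425 in Immune, 0.00899 to 0.0765 in Thin Limb and 0.00899 to 0.193 in Podocytes/Glom. Log2 ratios of shares were -0.98 to -0.76 in TAL, 0.91 to 1.29 in DCT2, 0.69 to 1.00 in CNT, 0.32 to 0.59 in DCT, 0.26 to 0.55 in Proximal s2/s3, -0.24 to -0.06 in Proximal s1/s2/s3, -0.34 to 0.19 in Proximal s1/s2, -1.12 to -0.39 in Thin Limb, -0.74 to -0.45 in OMCD principal, -0.0142 to 0.54 in CCD principal, -0.0501 to 0.38 in AIC, -0.17 to 0.0183 in BIC, -0.0612 to 0.27 in Podocytes/Glom, -0.54 to -0.04 in Immune and -0.0357 to 0.51 in mystery cells. Differences in cell-cycle cells, in percentage points, were 1.74 to 2.69 in DCT, 0.763 to 1.82 in CNT, 0.212 to 0.365 in TAL, 0.476 to 1.40 in DCT2, 0 to 1.43 in AIC, 0.0771 to 0.756 in CCD principal, -0.404 to 0.959 in Immune, -0.427 to 0.667 in OMCD principal, -0.109 to 0 in Proximal s1/s2, 0.0024 to 0.21 in Proximal s1/s2/s3, -0.137 to 0.094 in Proximal s2/s3, 0 to 3.57 in mystery cells, and 0 in BIC, Podocytes/Glom and Thin Limb. Uncalled genes that turned were Atp1b1 in TAL (-0.0048 to 0.25), Umod in TAL (-0.0202 to 0.26), Calb1 in DCT2 (-0.0723 to 0.16), Kcnj1 in DCT (-0.0461 to 0.12), Trpm6 in DCT (-0.0153 to 0.22), Mki67 in Immune (-0.77 to 0.22) and Scnn1a in BIC (-0.18 to 0.24).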

Other observations

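Several genes called in single classes had values in others that did not pass edgeR's test. Tfrc, which rose in DCT, DCT2 and CNT, had a log2 change of 1.73 ± 0.37 in CCD principal (adjusted p = 0.094) and -0.70 ± 0.28 in TAL (0.261). Birc5, which rose in DCT, had 2.51 ± 0.56 in TAL (adjusted p = 0.0553), on 1.26 to 4.56 CPM per vehicle library and 12.2 to 21.3 CPM per furosemide library. Ckb, which rose in DCT and DCT2, had 1.56 ± 0.44 in CNT (adjusted p = 0.083). Timp3, which fell in BIC and DCT, had -0.84 in Thin Limb (adjusted p = 0.12). Hspa1a, which fell in DCT, had -1.11 ± 0.26 in BIC (adjusted p = 0.0815) and 0.06 ± 0.27 in CCD principal (0.96). Whether these effects differ between those classes was not tested.

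Further values of injury genes and of genes of calcium and magnesium handling did not pass in single classes. Havcr1, the kidney injury molecule gene, had 1.33 ± 0.49 in the summed proximal classes (adjusted p = 0.6), and Lcn2 had 0.05 ± 0.92 there (0.99). Spp1 had 0.55 ± 0.20 in TAL (adjusted p = 0.21) and -0.51 ± 0.14 in CCD principal (0.11). The klotho gene Kl had 1.34 ± 0.28 in CCD principal, 0.61 ± 0.20 in CNT (adjusted p = 0.14) and 0.75 ± 0.30 in TAL (0.26). The magnesium channel gene Trpm6 had 0.86 ± 0.30 in CNT (adjusted p = 0.14), and the calcium channel gene Trpv5 had 0.28 ± 0.18 in CNT (0.48) beside its rise over whole libraries.

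Of the 4122 TAL cells, 54.2% ± 5.33 held both Cldn16 and Cldn10 in vehicle libraries and 68.8% ± 1.30 in furosemide libraries (SD, n = 3), without overlap between treatments, and 6 cells held neither.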
